A study of Caenorhabditis elegans with 4 samples.

How the data were processed

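The study profiled the DNA bound by a GFP-tagged ELT-1 protein in Caenorhabditis elegans by chromatin immunoprecipitation followed by sequencing (ChIP-seq). ELT-1 is a GATA-type zinc finger transcription factor known for its role in specifying epidermal cells. Hermaphrodites of strain OP354, which carries an elt-1 transgene fused to EGFP and FLAG together with an unc-119 rescue marker, were grown at 20 °C to the L3 larval stage and fixed with 2% formaldehyde, per the labels' protocols. Chromatin was sonicated and precipitated with anti-GFP antibodies, and a part of each extract was kept as input DNA. There were 4 samples, namely 2 ChIP samples and their 2 inputs, with replicate numbers taken from the sample titles. The labels do not say whether the 2 replicates came from separate worm cultures, so differences between them measure only the spread between these 2 samples.

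There were 3 lists, analysed as the authors deposited them, with coordinates in WormBase WS220 per the file headers: the binding regions of ChIP replicate 1, those of replicate 2, and 1 combined list. The source field of the deposited files names SPP, a ChIP-seq peak caller, and the irreproducible discovery rate (IDR), a method that rates regions by how alike they rank between replicates. The aligner, the versions, the thresholds, the way input was used and the rule that made the combined list are not given in the sources used here. Each region in the deposited files has 1 score set by the authors, whose meaning no field states. In the replicate lists the score was capped at its highest value, which 2507 regions (8.88%) of replicate 1 and 2733 regions (10.4%) of replicate 2 shared. In the combined list the same score stood beside all 2548 regions, so it ranks nothing there. The score was planned as the rank of every list. The region names also carry a number, which followed the score closely across regions (Spearman's rho -0.9996 in replicate 1 and -0.9994 in replicate 2). Regions were ranked by score with ties broken by this number, and the combined list by the number alone. Among the 2507 and 2733 regions at the cap the score sets no order, so this rho does not test the number there. The order of nearly all best-ranked regions below, and the cut at the best 2548 of replicate 2, thus rest on a number of unstated meaning. Across combined regions the number correlated with the best overlapping number of replicate 1 (rho 0.840) and of replicate 2 (rho 0.724). The read depth behind the regions is unknown, so no region has a counting interval of its own. Most regions had 1 set width per list (384 bp for 83.5% of combined, 376 bp for 99.2% of replicate 1 and 384 bp for 99.6% of replicate 2 regions), so for most regions width says little about the extent of binding. The best combined regions differed in this. Of the best 254, 238 (93.7%) had another width, and the median of the 254 was 223 bp.

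Lists were compared by overlap of at least 1 bp. The chance level came from 1000 circular shifts of one list within each chromosome, which keep widths, spacing and chromosome counts, as a one-sided permutation test whose smallest p is 0.001. Ranks were compared over mutual best pairs of overlapping regions with Spearman's rho and 100000 permutations of the pairing, two-sided, whose smallest p is 1e-05. Chromosome counts were tested against chromosome length with a chi-square test and exact binomial tests, adjusted by Benjamini-Hochberg over the 6 nuclear chromosomes, and ratios of regions per Mb have exact 95% intervals conditional on the total. Chromosome length was the largest coordinate of any list, 100.2 Mb in all. Regions are not independent replicates, so these p-values and intervals describe the lists and not a population of worm cultures. The outer 20% of a chromosome at either end was called an arm and the rest the centre. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap and shift functions were tested on simulated lists compared with the 26300 nuclear regions of replicate 2. In lists of 4000 regions planted overlap shares were recovered within 0.829 percentage points, and 3 of 100 lists of 1000 regions without planted overlap had p under 0.05. Apart from planted regions, simulated regions were placed uniformly along the chromosomes. The shifts do not hold dense parts of a chromosome in place. How the test behaves for 2 lists dense in the same parts was therefore not tested.

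The tests, the alternatives and the rule for named regions were fixed before the data were examined, except where the text says otherwise. Alternatives were a 50% reciprocal overlap, midpoints within 200 bp, the better part of each list, other numbers of best regions, and each replicate's best regions in place of the combined list. The named regions are the 15 best combined regions and the best on each chromosome. The planned tests of promoter location, of the WGATAR motif under the regions, of the motif by rank and of binding at fixed gene lists were not run. They need a WS220 sequence or annotation, which was not used here. The gene table at hand is of assembly WBcel235, and coordinates of different builds were not mixed. For the same reason regions are given by position and not by gene, and whether they are exonic, intronic or intergenic was not determined.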

Results

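Binding regions of ELT-1::GFP in L3 larvae were given as 1 list for each of the 2 ChIP samples and 1 combined list. Replicate 1 had 28238 regions and replicate 2 had 26327, of which 25 and 27 were on mitochondrial DNA. The combined list had 2548 regions, all nuclear. The replicate lists covered 10.2% and 9.68% of the nuclear genome, against 0.893% for the combined list. Read counts were not part of these lists, so depth is unknown and regions are compared by position and rank. How the input DNA entered the calling of regions is not given in the sources used here, and no separate background level was analysed.

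The first question was where the best-ranked binding regions of ELT-1::GFP lay. The best region of the combined list lay on chromosome IV at 9615324 to 9615967 and was also number 1 in both replicates, with midpoints 2 bp apart. The next was on V at 14506715 to 14507077, number 3 in both replicates. Number 3 was again on IV, at 9614093 to 9614503, near the best region, and number 10 lay close by at 9618061 to 9618399. The tagged gene, elt-1, is itself on chromosome IV, but whether these regions lie at it was not determined.

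The best region on X spanned 12671588 to 12671921 and was number 4 in the combined list, 10 in replicate 1 and 4 in replicate 2. On chromosome I the best was 8985879 to 8986274 (number 7), and on II it was 6176557 to 6176897 (number 8). Chromosome III had none of the 15 best, and its best region, 3867420 to 3867688, was number 17. Chromosome V held 6 of the 15 best: besides the region already given, these were at 19429597 to 19429939, 5425051 to 5425413, 4628459 to 4628781, 15660982 to 15661343 and 5523283 to 5523571. The others were on IV at 1911253 to 1911686, on I at 32622 to 32928 and on X at 15469942 to 15470315. Each of these 15 regions was within the best 28 of both replicates, their widths were 289 to 644 bp, and the replicate midpoints lay 0 to 54 bp apart. The combined list by which they were chosen was made from these replicates, so this likeness is not independent evidence.

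The second question was how far the replicates shared their regions. Of the 28238 replicate 1 regions, 10521 (37.3%) overlapped a replicate 2 region, against 18.4% ± 0.238 (SD over 1000 shifts) at shifted positions. In the other direction 10447 of 26327 (39.7%) overlapped, against 19.7% ± 0.265. Both shares were above every shift (circular-shift permutation test, one-sided, p = 0.001, the smallest 1000 shifts can give). The shared regions were concentrated at the top of each list. Among the best 2548 nuclear regions, 90.8% of replicate 1 (95% Wilson interval 89.6 to 91.8) and 91.4% of replicate 2 (90.2 to 92.4) had a partner anywhere in the other list. In the next 2548 the shares were 61.9% and 56.8%, and at ranks 22933 to 25480 they were 22.8% and 26.6%. At those ranks the shifted positions gave 18.3% and 19.6%, a smaller excess that still passed the permutation test (p = 0.001 in both directions). In the last, smaller bins, of 185 and 820 regions, the shares were 24.3% and 24.8%, and the highest shifts gave 26.5% and 24.8% (permutation p = 0.018 and 0.002).

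**Figure D1:**
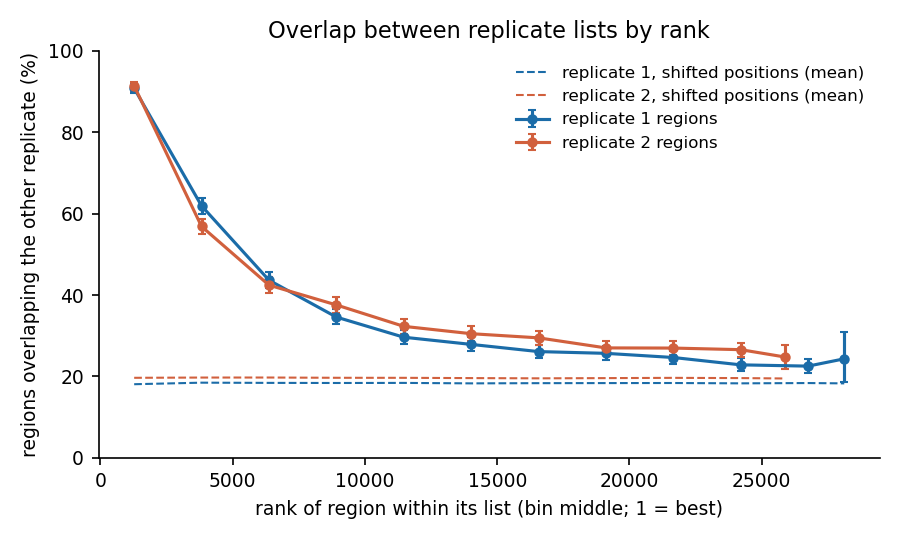
Share of nuclear regions overlapping the other replicate's list (vertical axis, %) by rank within the list (horizontal axis, middle of bins of 2548 regions with a smaller last bin, best on the left). Points are the 2 replicates with 95% Wilson intervals and dashed lines the mean of 1000 circular shifts; the shares fall from 90.8% and 91.4% in the best bin toward the shifted level.

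When only the 2548 best regions of each replicate were set against each other, 1556 (61.1%) of replicate 1 and 1574 (61.8%) of replicate 2 were shared, against 2.68% and 2.94% at shifted positions (permutation test, p = 0.001 for both). These sets include mitochondrial regions. With the 2548 best nuclear regions, a setting added after seeing the data, the shares were 60.6% and 61.1%. Shifted positions then gave 1.89% and 1.92%. Across 9403 mutual pairs of overlapping regions the scores correlated with a Spearman's rho of 0.502 (permutation of pairings, p = 1e-05, the smallest possible), a correlation across regions within these 2 samples. Since shifted positions gave 18.4% overlap against 37.3%, some pairs must be chance ones, more often at low ranks. Mixing these with shared regions at the top can itself raise rho, and permuting the pairing does not remove this. The score was at its cap in one or both replicates for 94.1% of the 2513 pairs that overlapped a combined region. Among those pairs the scores did not correlate detectably (rho 0.0187, permutation p = 0.351), whereas the numbers in the region names, which have no cap, gave rho 0.444 (permutation p = 1e-05; chosen after seeing the data).

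The third comparison was of the combined list with its replicates, from which it was made, so the overlap is not independent evidence of binding. Of 2548 combined regions, 2485 (97.5%) overlapped a region of both replicates, against 6.52% at shifted positions (permutation test, p = 0.001). A further 62 overlapped replicate 1 only and 1 overlapped replicate 2 only, a departure from an even split (exact binomial test, p = 1.39e-17). Against the 2548 best regions of each replicate, a setting added after seeing the data, 84.5% of combined regions were found in replicate 1 and 72.6% in replicate 2, and 59.9% in both. Where both replicates had a region, their midpoints were a median of 38 bp apart. That distance was 23 bp in the best 20% of combined regions by number and 61 bp in the last 20%.

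The fourth question was how the regions were spread over the chromosomes. X carried 594 combined regions, or 33.5 per Mb, and the autosomes together 1954, or 23.7 per Mb. The density on X was thus 1.42 times that of the autosomes (95% interval 1.29 to 1.55). X held 23.3% of the regions on 17.7% of the length (exact binomial test, adjusted p = 4.03e-12 over 6 chromosomes). Chromosome V, with 20.3 regions per Mb, and IV, with 20.8, were below their share by length (exact binomial adjusted p = 3.11e-07 and 3.67e-05). Part of these deficits was shared by all called regions. V held 0.799 times its share in the combined list, and 0.860 and 0.881 times in the whole lists of replicates 1 and 2. For IV the values were 0.819, 0.932 and 0.964. Chromosomes I, II and III had 24.6, 27.8 and 26.8 regions per Mb and were not detectably different from their share in this list (exact binomial adjusted p = 0.542, 0.0755 and 0.314). For II this call depended on the list: among the best regions of replicates 1 and 2 it held 1.12 and 1.11 times its share (exact binomial adjusted p = 0.0151 and 0.0278). The best 2548 regions of each replicate alone gave X-to-autosome ratios of 1.38 and 1.36. A smaller excess was present in the whole nuclear lists, at 1.09 (95% interval 1.06 to 1.12) in replicate 1 and 1.06 (1.03 to 1.09) in replicate 2. Below the best 2548 regions the ratios were 1.06 (1.03 to 1.09) and 1.03 (0.996 to 1.06).

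**Figure D2:**
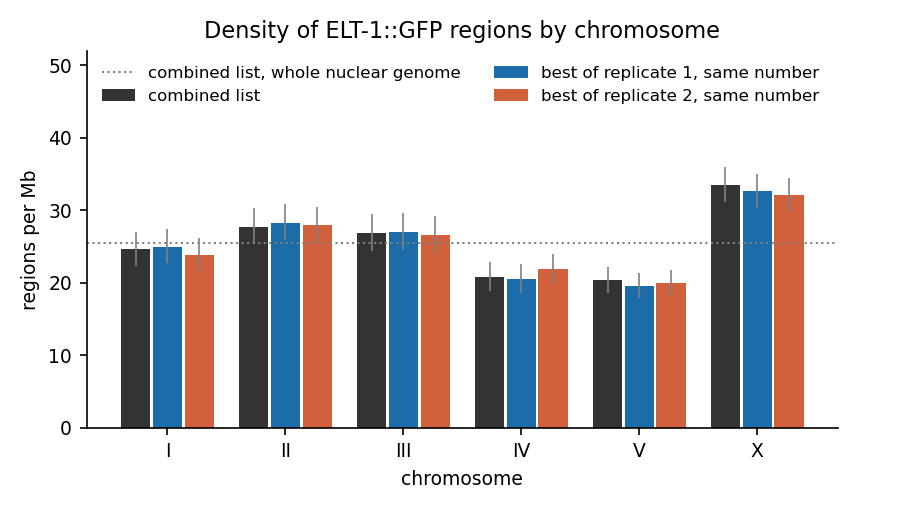
Regions per Mb (vertical axis) on the 6 nuclear chromosomes (horizontal axis) in the combined list and in the 2548 best regions of each replicate, without their mitochondrial regions. Error bars are exact 95% binomial intervals and the dotted line is the combined list's nuclear mean of 25.4 per Mb; X is highest, at 33.5 per Mb in the combined list, in all 3 sets.

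X also differed in how its regions lay along it, a comparison made after seeing the data. On the autosomes the centre held 29.7 combined regions per Mb and the arms 14.6, a ratio of 2.03 (95% interval 1.83 to 2.25; exact binomial test, p = 7.88e-46). Each autosome had the denser centre, with ratios from 1.73 on I to 2.97 on V. On X the centre held 34.1 and the arms 32.7 regions per Mb, a ratio of 1.04 (0.880 to 1.23; exact binomial p = 0.645). The arms of X were unlike each other, with 26.5 regions per Mb at the start of the chromosome and 38.9 at its end (94 and 138 regions; exact binomial p = 0.00465), so the pooled ratio averages a sparser and a denser end. In the best regions of replicates 1 and 2 the ends held 90 and 126 and 88 and 115 regions (exact binomial p = 0.017 and 0.0678). The balance of centre and arms differed between the autosomes and X with an odds ratio of 1.95 (1.60 to 2.38; Fisher's exact test, two-sided, p = 2.84e-11). X therefore exceeded the autosomes 2.24-fold in the arms (1.90 to 2.62) and 1.15-fold in the centre (1.02 to 1.29). The same contrast in the best 2548 nuclear regions of replicates 1 and 2 gave odds ratios of 1.81 and 1.73 (Fisher's exact p = 7.14e-09 and 1.29e-07). Within X itself the lists differed in their call: the centre-to-arm ratio was 1.14 (0.958 to 1.35; exact binomial p = 0.14) in replicate 1 and 1.23 (1.03 to 1.46; exact binomial p = 0.0194) in replicate 2, where the centre was denser.

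**Figure D3:**
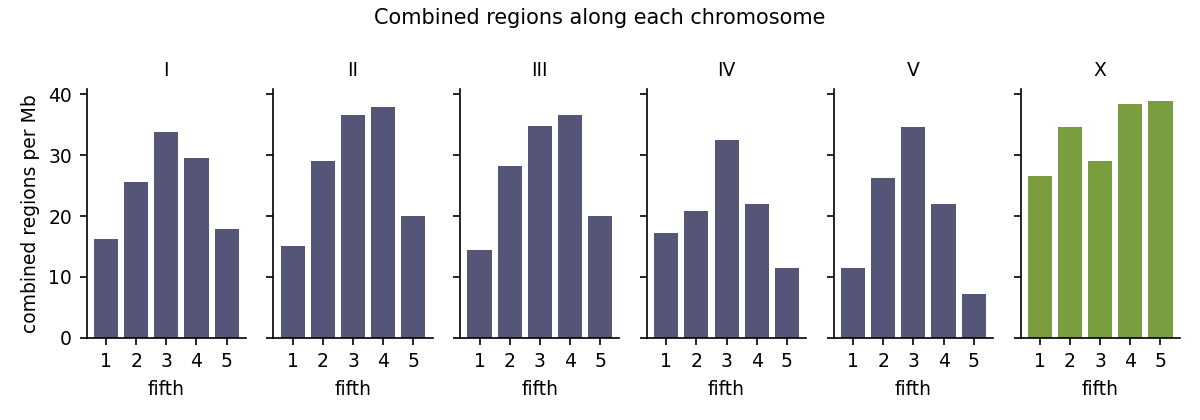
Combined regions per Mb (vertical axis) in 5 equal parts of each chromosome (horizontal axis, numbered from the start), autosomes in grey-blue and X in green. On chromosome V the density goes from 11.5 to 34.7 and back to 7.17 per Mb, whereas on X it lies between 26.5 and 38.9 per Mb.

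Combined regions also lay close together more often than regions placed at random, in a comparison that was not among the planned tests. A neighbour midpoint within 2 kb was found for 26.8% of them, against a mean of 9.96% in 1000 uniform sets with the same chromosome counts and 11.5% in 1000 sets drawn from lower-ranked replicate 1 regions (permutation tests, one-sided, p = 0.001 for each, the smallest possible). Of the combined regions, 43 overlapped the next one, and overlapping or repeated regions were not joined before this count. Joining such neighbours left 2160 separate places, of which 1866 were single regions without such a neighbour. Of the clusters, 238 held 2 regions, 56 held 3 or more and 6 held 5 or more. The clusters described next were chosen after their values were seen. The largest, on IV from 9607040 to 9619135, held 12 regions within 12.1 kb, and 3 of these were among the 15 best of the genome, 6 among the best 100 and 10 among the best 500. Midpoints of neighbours in it were 659 to 1887 bp apart. The next held 8 regions on X at 10764954 to 10771421, and 2 clusters held 6 each, on V at 4505520 to 4509817 and on II at 6827322 to 6833315. Clusters of 5 lay on I at 8985879 to 8989940, which begins with the best region of that chromosome, and on X at 13141386 to 13146565.

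**Figure D4:**
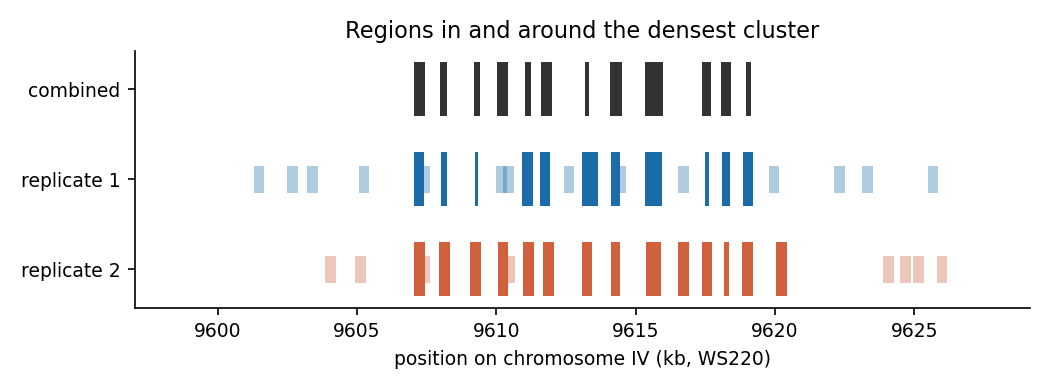
Regions of the combined list and of each replicate (rows) in and around the cluster on chromosome IV (horizontal axis, kb in WS220). Tall bars are regions at the highest score of their list and short pale bars the others; the combined row shows the 12 regions between 9607040 and 9619135.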

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

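The values in this part were chosen after the data had been seen, and no explanation was tested.

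Mitochondrial DNA, outside the nuclear comparisons, carried 25 regions in replicate 1 and 27 in replicate 2, and 0 in the combined list. Many of these entries repeat an interval. In replicate 1 the 25 entries were 8 distinct intervals, and 22 shared their coordinates with another entry. In replicate 2 the 27 entries were 2 distinct intervals, and 26 shared one interval of 13372 bp. Together the intervals covered 96.9% of the mitochondrial DNA in replicate 1 and 98.0% in replicate 2. Since entries repeat the same intervals, their number is no measure of signal. Counting repeated entries, 13 were among the best 100 in each replicate. Their numbers ran from 2 to 16145 in replicate 1 and from 2 to 1936 in replicate 2. Whether the input DNA gave the same regions was not analysed here.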

How the results depend on the processing

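The overlaps of whole lists, of their best regions and of the combined list with both replicates stayed above all of their 1000 shifts under each alternative, which was not so in the last rank bins. The share of replicate 1 regions with a partner was 26.3% with a 50% reciprocal overlap and 27.5% with midpoints within 200 bp, against 37.3%, so the level depends on the definition and the direction does not. The X-to-autosome ratio was 1.46 in the better 1274 combined regions, 1.55 in the best 500 and 1.38 and 1.36 with replicate 2 and replicate 1 left out, and passed the exact binomial test in each. The correlation of scores between replicates fell from 0.502 to 0.0187 when only pairs overlapping a combined region were kept. In those pairs the score was at its cap in both replicates for 57.9%, and the uncapped numbers in the region names gave 0.444. The merging of neighbours, the best 500 combined regions, the nuclear-only lists and the ranking by number were added after the data were seen. The alternatives planned for promoter location, GATA motif, motif by rank and gene list binding were not run, since these tests need a WS220 sequence or annotation. No replicate could be left out of the comparison of the 2 replicates with each other. No paired analysis was possible because no file of the input samples was analysed here, so ChIP and input share no fit. Depth limits what can be said of the lower ranks: with unknown read counts, a region absent from one list cannot be called unbound there.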

Other observations

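The values and tests in this part were chosen after the data had been seen, and only the bound for the ratio of merged neighbours was set before that ratio was computed. Some well-ranked regions had no partner in the other replicate, and the replicates differed in how these entered the combined list. Of the 2548 best nuclear regions, 235 in replicate 1 (9.22%) and 220 in replicate 2 (8.63%) overlapped nothing in the other list. Of these, 66 of the replicate 1 regions overlapped a combined region, against 1 of the replicate 2 regions. The best unmatched region of replicate 1 was number 487, on V at 538373 to 538748, and it was in the combined list. The best of replicate 2 was number 248, on III at 4015769 to 4015991, and it was not.

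A pair of overlapping stretches on II, at 8418717 to 8420076 and 8420006 to 8421604, each stood in the combined list under 2 numbers with the same coordinates (785 and 1320, and 523 and 618). At 1360 and 1599 bp they were the widest combined regions. The same place was listed 6 times in replicate 2. Counting repeated regions once left the X-to-autosome ratio at 1.42.

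The excess of combined regions on X, most of it in the arms, was weighed against 3 technical explanations. Counting neighbours singly does not account for it, because merging regions within 2 kb left the X-to-autosome ratio at 1.42 (95% interval 1.28 to 1.57). An excess on X shared alike by all called regions is too small. X was more frequent among the 2548 best nuclear regions than among the rest. The odds ratios were 1.31 (1.18 to 1.44) in replicate 1 and 1.32 (1.20 to 1.46) in replicate 2 (Fisher's exact test, p = 1.48e-07 and 4.28e-08). Thinning of all called regions alike toward the autosomal ends is also too weak. Odds of an autosomal centre were 1.75 (1.57 to 1.95) and 1.87 times (1.68 to 2.09) as high for the best as for the rest. Neither comparison with the rest could show a technical effect confined to the best regions. Nor could either show an effect common to all real signal. At low ranks the overlap between replicates neared the shifted level, so spurious calls there could dilute such an effect. No input was analysed here, so such effects stay open. Also open are untested hypotheses. The distribution of genes or of open chromatin along the chromosomes may differ between X and autosomes, or ELT-1 itself may prefer X. No biological explanation was tested.

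The cluster of 12 regions on IV was larger than a random order of the gaps between neighbouring combined regions gave. With these gaps reordered within 5 equal parts of each chromosome, 0 of 1000 sets held a cluster as large, though the largest in any set held 11. This covers only the order of the gaps and does not say what gave the cluster. The strain carries an elt-1 transgene, so extra copies of the DNA around it could raise the signal over the whole stretch. Regions outside the combined list were 1.36 times (95% Poisson interval 0.725 to 2.33) as dense in the 20 kb on either side as on IV at large in replicate 1 and 1.20 times (0.599 to 2.15) in replicate 2. These intervals are too wide to tell no change from a rise, so extra copies and binding cannot be told apart here. The span of the transgene, the use of input in calling and whether the cluster lies at elt-1 keep this open, and no biological explanation was tested.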
